A study of Mus musculus with 6 samples.

How the data were processed

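Bulk 3' end MARS-seq libraries of sorted mouse thymic tuft cells cultured ex vivo were compared between rIL-13 and vehicle, 3 libraries each. Groups and replicate numbers were taken from the sample titles. Reads were processed with bcl2fastq, cutadapt, STAR 2.5.2b, HTSeq and DESeq2 on genome build mm10, per the submitters' processing notes, which give no roles or order for these tools. The deposited table holds, per the file headers, raw counts of unique molecular identifiers per gene, counts divided by size factors, regularized log2 values and the columns of a comparison by the authors. Each of the 9088 genes in it has at least 6 UMIs in some library, so totals are sums over listed genes and not the whole depth of a library. The deposited counts were used for every test here. The authors' normalized signal was used only to recover their size factors, which ran from 0.746 in rIL-13 replicate 3 to 1.43 in vehicle replicate 3. The deposited log2 values after the regularized transformation were not used. The authors' log2 fold changes and p-values are given as theirs, with the sign turned so that positive means higher with rIL-13. The baseline mean over all libraries that the authors list as a normalized signal was not used.

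Genes were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test with robust estimation, TMM factors and group as the single term, after its default filter on low counts by group. The filter kept 5135 genes with 93.8% of UMIs, and the biological coefficient of variation was 24.9%. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Standard errors of log2 fold changes are those implied by the F statistic. Chga, Syt5, Tnni3, Il25 and Dclk1 fell under the filter and are given from the same fit with at least 1 UMI as the single requirement. CPM values are scaled by TMM factors. Counting error is part of each standard error, and it is large for genes with a few UMIs per library.

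Gene lists were tested with limma 3.58.1, by camera with a preset correlation between genes of 0.01 on log2 CPM with a prior count of 2, and beside it by camera with an estimated correlation and by fry, for lists with 5 or more tested members. Adjusted p-values run over the 16 tested lists. Shares of UMIs and depth were compared by two-sided exact permutation tests, whose smallest p is 0.1. The 26 lists, the designs and the alternatives were fixed before the data were examined. Named genes were the 12 with the smallest p in each direction among those past the threshold, or all where fewer passed, the 2 tested members with the smallest p of each tested list, and 11 genes fixed in advance (Il13ra1, Il4ra, Stat6, Socs1, Cish, Pou2f3, Trpm5, Dclk1, Il25, Mki67 and Cd74). Genes without a proper symbol were passed over, and a direction with no gene past the threshold would have given its 5 smallest p as values that did not pass. The rule gave 3 genes by p and 32 by list, 2 of the latter past the threshold. Of those that did not pass, some are left out of the text, and 1 member of the tuft cell list is not reported here. Genes of the authors' deposited comparison that passed there were added, and other genes named outside the rule were chosen after their values were seen. These include Sh2d6, Sh2d7, Spib, Pdgfrb, Epcam, Ptgs1, Tas1r1, Tnni3, Tnnt1 and Ptprh. Coordinates come from GENCODE M21 on mm10, in which 8966 of the 9088 symbols were found.

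The gene and list tests, and DESeq2 1.42.0 and limma voom as alternatives, were tested on simulated data, with counts drawn from the real means, spread and library sizes of 5135 genes, 200 of them changed, in 5 draws. On these counts edgeR called 0.182% of unchanged genes. Alternatives tried were DESeq2, limma voom, other scaling factors, filters and thresholds, a replicate term, a total without ribosomal protein genes, 3 UMIs in place of 1 for detection, and leaving out each library in turn. Leaving out a pair of libraries together, thinning to equal depth and a tuft cell list without Ptpn18 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.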

Results

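Thymic tuft cells are rare chemosensory epithelial cells of the thymic medulla that share taste-type signalling genes with the tuft cells of the gut and airway. They were sorted from thymi of young wild-type male mice, spun into aggregates and cultured for 12 h, then for 24 h in fresh medium. Recombinant interleukin 13 (rIL-13), a type 2 cytokine that signals through STAT6 in many epithelia, was then added at 20 ng/mL for 24 h, and control wells received the PBS vehicle. Polyadenylated RNA was profiled in bulk by MARS-seq, a method that counts unique molecular identifiers (UMIs) at the 3' end of transcripts, in 3 libraries of each group. The comparison asks which transcripts of cultured thymic tuft cells differ after exposure to rIL-13. The labels do not say whether the replicates are separate cultures or animals, so every p-value measures the spread between these 6 libraries, which may be technical.

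The 9088 listed genes held 394513, 457823 and 489919 UMIs in vehicle replicates 1, 2 and 3, and 295614, 287198 and 248028 in rIL-13 replicates 1, 2 and 3. The rIL-13 libraries were thus shallower, at 276947 ± 25395 UMIs (mean ± SD, n = 3) against 447418 ± 48547 in vehicle (n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). At least 1 UMI was found for 8715 ± 69.1 genes with rIL-13 and 8914 ± 60.7 with vehicle (SD, n = 3 each). The most similar pair of libraries, by Spearman correlation across genes, was vehicle replicate 3 with rIL-13 replicate 1, at 0.886, and the least similar was rIL-13 replicate 1 with rIL-13 replicate 3, at 0.776. Every pair of libraries differed by more than counting noise, with a chi-square of 2.72 to 5.81 per degree of freedom, so no library was a copy of another.

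Of 5135 genes tested, 3 changed with rIL-13. Dnaaf3, which encodes an assembly factor of the dynein arms of cilia, rose 16.2-fold, by a log2 fold change of 4.02 ± 0.41 (SE, n = 3 per group; edgeR adjusted p = 6.5e-05). Its UMIs were 3, 3 and 4 in the vehicle libraries and 29, 47 and 31 in the rIL-13 libraries. Ptpn18, a protein tyrosine phosphatase of the tuft cell list, rose 2.90-fold, by 1.54 ± 0.26 (edgeR adjusted p = 0.0204), from 313 ± 66.9 to 909 ± 283 CPM (UMI counts scaled to library size by TMM; SD, n = 3 each). Des, which encodes the muscle intermediate filament desmin, fell, with a log2 fold change of -1.70 ± 0.28 (edgeR adjusted p = 0.0204) and 239 ± 60.0 CPM with vehicle against 73.4 ± 6.76 with rIL-13. All 3 rIL-13 libraries lay above, or for Des below, all 3 vehicle libraries. In mm10 coordinates Dnaaf3 lies on chromosome 7 at 4522933 to 4532453 on the minus strand, Ptpn18 on chromosome 1 at 34459762 to 34475733 and Des on chromosome 1 at 75360329 to 75368579, both on the plus strand, and all are annotated as protein-coding. At an unadjusted p under 0.05, edgeR gave 282 genes, 158 higher and 124 lower, against 256.75 that chance would give, and the libraries of the groups did not overlap for 601 genes, or 11.7%, against 10% by chance.

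Dnaaf3 passed with every library left out in turn. Ptpn18 and Des did not pass without vehicle replicate 1 (edgeR adjusted p = 0.271 and 0.0590), vehicle replicate 2 (0.0611 for both), rIL-13 replicate 2 (0.20 and 0.215) or rIL-13 replicate 3 (0.165 for both), and with limma voom no gene passed (adjusted p = 0.0562 for Dnaaf3, Ptpn18 and Des). Without rIL-13 replicate 1 the count rose to 20 genes higher and 9 lower, and without vehicle replicate 3 to 8 higher and 15 lower.

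**Figure D1:**
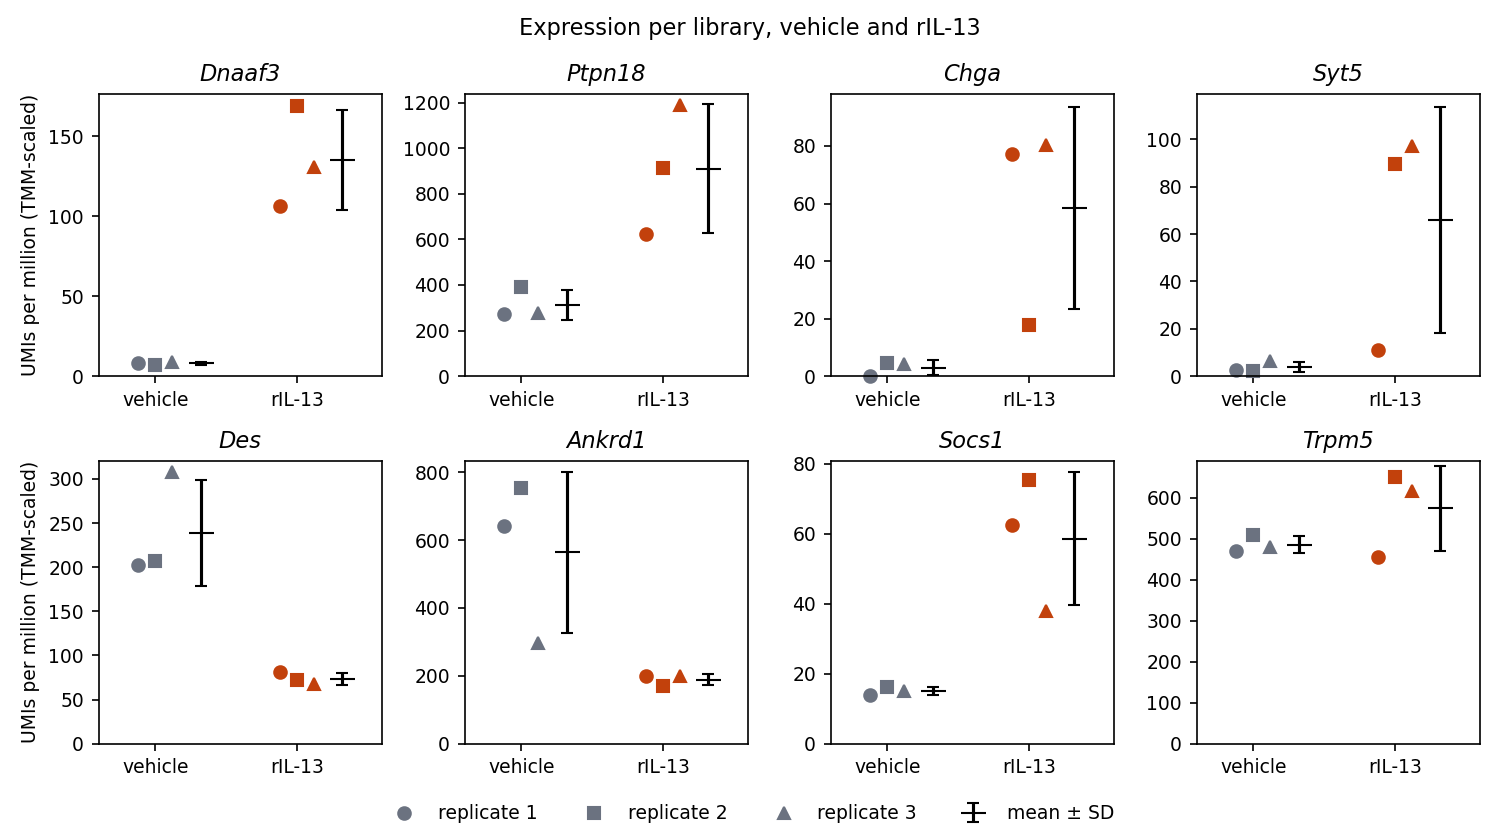
CPM of 8 genes in each library (vertical axes, linear, from 0, scaled by TMM factors) for vehicle and rIL-13 (horizontal axes), with replicates 1 to 3 as circles, squares and triangles and the mean ± SD in black. Dnaaf3 lay between 6.96 and 8.68 in the vehicle libraries and between 107 and 169 in the rIL-13 libraries, while Trpm5, which did not pass the test, overlapped between the groups.

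The authors' deposited table, made with DESeq2, held 6 genes past their criteria, 4 higher with rIL-13 and 2 lower. Besides Dnaaf3, Ptpn18 and Des, the authors' deposited table held Chga, Syt5 and Ankrd1, at adjusted p = 0.0332, 0.0332 and 0.00955. Chga encodes chromogranin A, a protein of secretory granules, and Syt5 a synaptotagmin, a calcium sensor of vesicle release. Both fell under the count filter used for edgeR, and in the edgeR fit without a filter they rose, by a log2 fold change of 4.03 ± 0.72 (SE, n = 3 per group; adjusted p = 0.0112) for Chga and 3.90 ± 0.72 (adjusted p = 0.0273) for Syt5. Chga had 0, 2 and 2 UMIs in the vehicle libraries and 21, 5 and 19 with rIL-13. Syt5 had 1, 1 and 3 UMIs with vehicle and 3, 25 and 23 with rIL-13, so that rIL-13 replicate 1 lay nearer the vehicle libraries than its own group. Neither passed without vehicle replicate 1 (edgeR adjusted p = 0.214 for Chga and 0.532 for Syt5), vehicle replicate 2 (0.156 and 0.455) or rIL-13 replicate 3 (0.144 and 0.158), nor did Syt5 without rIL-13 replicate 2 (0.311). Ankrd1, an ankyrin repeat protein of muscle and a known target of the transcriptional coactivator YAP, had 564 ± 237 CPM with vehicle and 189 ± 17.1 with rIL-13 (SD, n = 3 each). Its log2 fold change of -1.58 ± 0.30 did not pass in the filtered edgeR fit (adjusted p = 0.0848) and passed without a filter (adjusted p = 0.0210).

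Syt5, at 4539765 to 4547541 on chromosome 7, and Dnaaf3 are neighbours on the same strand. The next gene on that strand, Tnni3, which encodes cardiac troponin I, lies at 4518305 to 4524229 and overlaps the 3' end of Dnaaf3. Tnni3, chosen after its values were seen, had 5, 2 and 1 UMIs with vehicle and 7, 11 and 14 with rIL-13, and its log2 fold change of 2.57 ± 0.65 in the unfiltered fit did not pass (edgeR adjusted p = 0.227). How reads in the overlap of Dnaaf3 and Tnni3 were assigned is not stated in the labels. The flanking genes Tnnt1 (-0.60 ± 1.63) and Ptprh (0.12 ± 1.09) did not pass either.

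**Figure D2:**
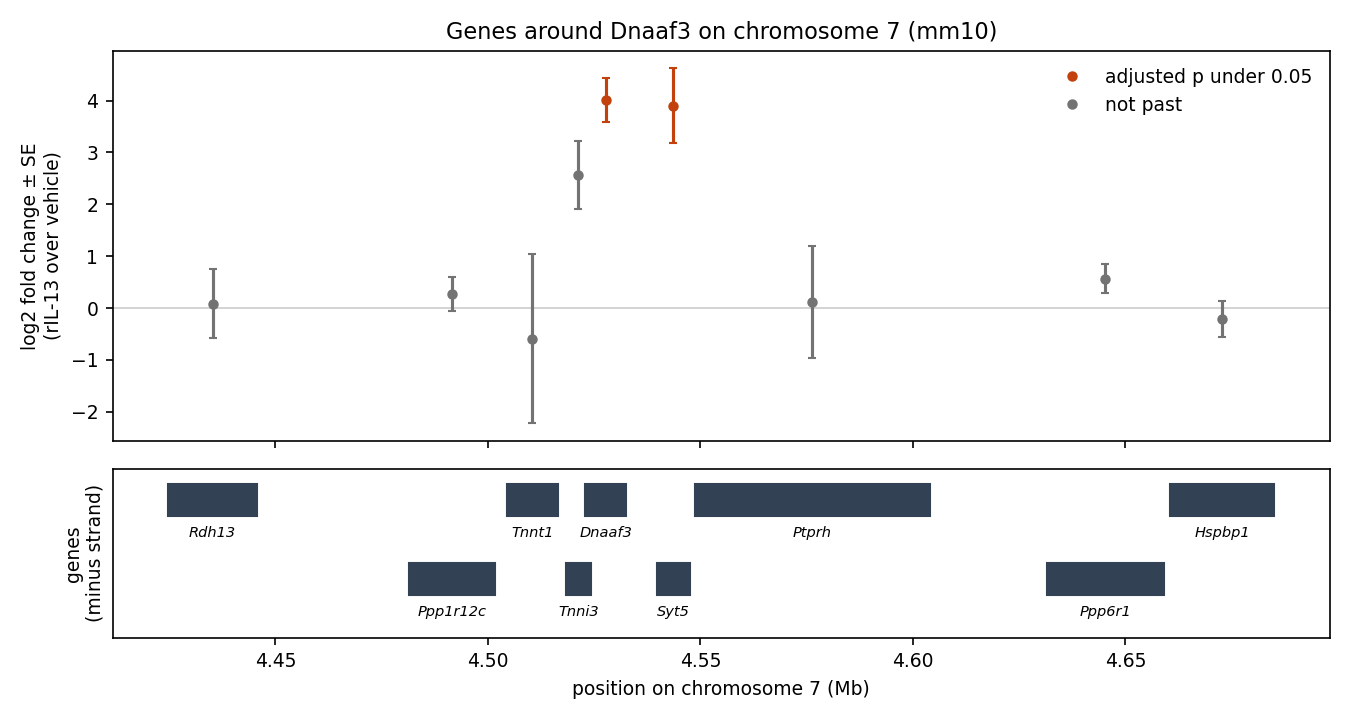
Log2 fold change of rIL-13 over vehicle (upper vertical axis, points, bars ± SE, unfiltered edgeR fit, n = 3 per group) of the listed genes around Dnaaf3 against position on chromosome 7 in Mb (horizontal axis, mm10), with the genes drawn to scale below, all on the minus strand. Dnaaf3 (4.01 ± 0.43) and Syt5 (3.90 ± 0.72) passed, Tnni3 between Tnnt1 and Dnaaf3 was at 2.57 ± 0.65, and Tnnt1 (-0.60 ± 1.63), Ptprh (0.12 ± 1.09) and Ppp6r1 (0.57 ± 0.28) did not pass.

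Tuft cell genes rose as a group in the preset test, and not in the others. Of 33 tested members of the list, 26 had a positive log2 fold change, with a median of 0.45 (limma camera with a preset correlation of 0.01, adjusted p = 6.6e-06). The call was lost with the correlation estimated from the data (adjusted p = 0.93 with an estimated correlation) and with fry (adjusted p = 0.741). Over all genes tested 1 member passed, Ptpn18, and adjusted over the list alone 6 members passed, all higher. Besides Ptpn18 these included the SH2 domain genes Sh2d7 (0.89 ± 0.29) and Sh2d6 (0.69 ± 0.23), the kinase gene Matk (0.79 ± 0.25) and the transcription factor gene Spib (0.73 ± 0.25), each with edgeR adjusted p = 0.0488 over the list alone. Trpm5, the cation channel gene of the taste-type cascade, had a log2 fold change of 0.24 ± 0.22 (edgeR adjusted p = 0.926). Pou2f3, the transcription factor that specifies tuft cells, was at -0.09 ± 0.50 (edgeR adjusted p = 0.993), from 31.5 ± 15.5 CPM with vehicle and 30.1 ± 8.05 with rIL-13. The mean score of the tuft list was 0.56 and 0.70 above the vehicle mean in rIL-13 replicates 2 and 3 and -0.12 in rIL-13 replicate 1, which lay within the range of the vehicle libraries, -0.12 to 0.13. Leaving out each library in turn kept the camera call with the preset correlation, at adjusted p between 2.5e-11 and 0.0129.

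Fibroblast markers fell as a group in the preset test. Of 10 tested members, 9 had a negative log2 fold change, with a median of -0.51 (camera adjusted p = 0.0233, and adjusted p = 0.93 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The collagen genes Col6a1 and Col3a1 were at -1.23 ± 0.60 and -0.83 ± 0.45, and Pdgfrb, a receptor of mural cells and fibroblasts, was at 0.41 ± 0.67. The score of the list was -0.09, -0.35 and -1.40 in rIL-13 replicates 1, 2 and 3 against -0.14 to 0.11 in the vehicle libraries. The call ended without rIL-13 replicate 3 (camera adjusted p = 0.685), vehicle replicate 1 (0.136) or vehicle replicate 3 (0.0709), where the median was -0.22, -0.23 and -0.42. It was -0.79 without rIL-13 replicate 1.

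**Figure D3:**
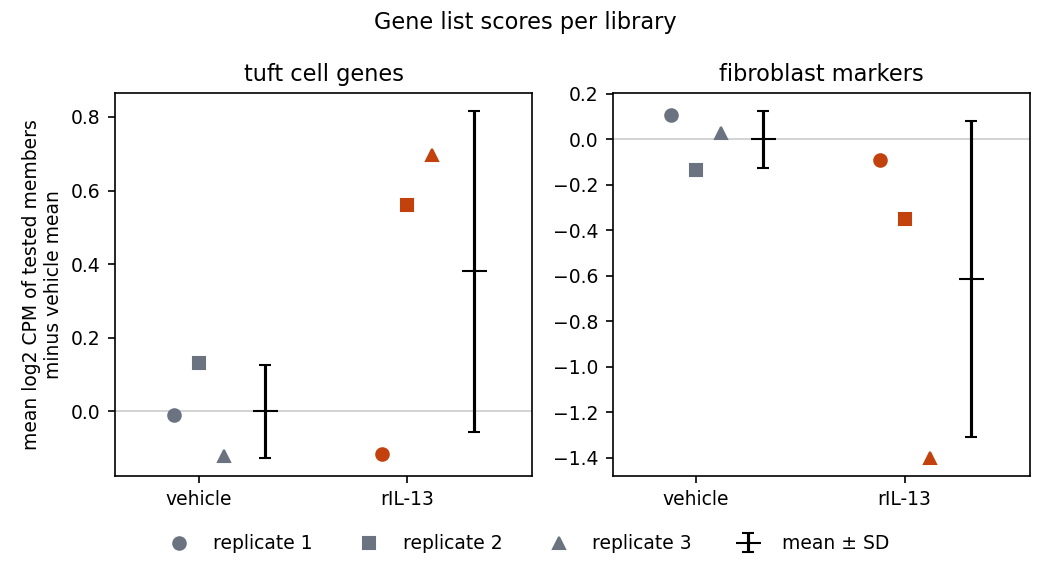
Mean log2 CPM of the tested members of the tuft cell list (left) and of the fibroblast list (right), minus the vehicle mean (vertical axes), in each library of the vehicle and rIL-13 groups, with the mean ± SD in black. The tuft score was 0.56 and 0.70 in rIL-13 replicates 2 and 3 and -0.12 in replicate 1, and the fibroblast score reached -1.40 in rIL-13 replicate 3.

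The 12 listed fibroblast markers held 0.435 ± 0.107% of UMIs with vehicle and 0.339 ± 0.116% with rIL-13 (SD, n = 3 each; two-sided exact permutation p = 0.3), and the 42 listed tuft cell genes 1.34 ± 0.154% and 1.77 ± 0.524% (exact p = 0.4). Thymocyte markers held 0.00756 ± 0.00778% and 0.00693 ± 0.000867%, with 3 of 25 markers listed. Myeloid and dendritic markers held 0.0139 ± 0.00743% and 0.00574 ± 0.00650%, B cell markers 0.00649 ± 0.000887% and 0.00738 ± 0.00306%, endothelial markers 0.0163 ± 0.00887% and 0.0105 ± 0.00208%, and ILC2 markers 0.00176 ± 0.00107% and 0.00200 ± 0.00189%. Other mimetic cell markers, those of the muscle-like, keratinized and further thymic epithelial types that imitate peripheral tissues, held 0.152 ± 0.153% with vehicle and 0.0656 ± 0.0343% with rIL-13, and 0.326% in vehicle replicate 3 alone. No erythroid marker and no mitochondrially encoded transcript is among the listed genes. Des was the single member of the other mimetic list to pass, over all genes and adjusted over the list alone, among 6 tested members, and the list was not called (median -0.57, camera adjusted p = 0.721). Of the thymic epithelial genes, none of 9 tested members passed, with a median of 0.22 and a mean of -0.01, the test pointing up with the median (camera adjusted p = 0.721). The epithelial adhesion gene Epcam was at 0.22 ± 0.29.

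Targets of IL-4 and IL-13 signalling through STAT6 were not called as a list. Of 44 genes in it, 16 were listed and 7 were tested, with a median of 0.00 and a mean of 0.22, the test pointing up with the mean (camera adjusted p = 0.721). The mean score of these 7 was higher in every rIL-13 library (0.22, 0.20 and 0.12) than in every vehicle library (0.11, 0.07 and -0.18), at the smallest exact permutation p, 0.1. Chance would separate the groups, in either direction, for 10% of lists, and the nearest scores here were 0.115 with rIL-13 and 0.113 with vehicle. The mean log2 fold change turned to -0.07 with at least 10 UMIs in 3 libraries as the filter and to -0.13 with every library thinned to the smallest total. No member passed over all genes and 1 passed adjusted over the list alone. This was Socs1, the feedback inhibitor of cytokine receptors, at 1.93 ± 0.46 (edgeR adjusted p = 0.255 over all genes and 0.00347 adjusted over the list alone). Its UMIs were 5, 7 and 7 with vehicle and 17, 21 and 9 with rIL-13, higher in 3 of 3 rIL-13 libraries. The filter of 10 UMIs in 3 libraries dropped Socs1 and left 6 members, so Socs1 carried the positive mean of the list. Cish, another feedback inhibitor of the family, was at 0.00 ± 0.41, and Stat6 itself at -0.30 ± 0.32 (edgeR adjusted p = 1.0 and 0.935). Il4ra and Il13ra1, which encode the receptor chains for IL-13, are not analysed here.

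The list of type 2 cytokines and enzymes of eicosanoid synthesis was not called (7 tested, median -0.06, mean 0.05, direction of the test up, camera adjusted p = 0.721). All 7 tested members were enzymes, so the list test says nothing on the cytokines. No member passed over all genes or adjusted over the list alone. The leukotriene enzymes Alox5 and Ltc4s were at 0.59 ± 0.23 and 0.49 ± 0.21 (edgeR adjusted p = 0.804 and 0.854), and the prostaglandin enzyme Ptgs1 was at -0.34 ± 0.25. Il25, the tuft cell cytokine that activates type 2 lymphoid cells, had 8, 9 and 9 UMIs with vehicle and 4, 6 and 11 with rIL-13, a log2 fold change of 0.35 ± 0.55 in the unfiltered fit (edgeR adjusted p = 0.975). Dclk1, a kinase used as a tuft cell marker, was at 0.98 ± 0.45 in the same fit (edgeR adjusted p = 0.896).

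Cell cycle genes were not called (25 tested, median -0.08, camera adjusted p = 0.855). Over all genes no member passed, and adjusted over the list alone 1 did, Ccnd1, which encodes the G1 cyclin D1, at 1.62 ± 0.37 (edgeR adjusted p = 0.255 over all genes and 0.00896 adjusted over the list alone). Its UMIs were 9, 23 and 37 with vehicle and 40, 35 and 55 with rIL-13. The proliferation marker Mki67 was at 0.21 ± 0.48 (edgeR adjusted p = 0.976) and the mitotic gene Ube2c at -0.64 ± 0.27 (0.832).

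Antigen presentation genes stayed under the threshold too (12 tested, median -0.03, mean 0.07, direction of the test up, camera adjusted p = 0.753), with Cd74, the invariant chain of class II molecules, at -0.22 ± 0.39 (edgeR adjusted p = 0.963). The p53 and apoptosis list had a median of -0.33 (9 tested, camera adjusted p = 0.277), with the p53 targets Mdm2 and Cdkn1a at -0.79 ± 0.32 and -0.53 ± 0.24. Its score was lower in every rIL-13 library than in every vehicle library (exact permutation p = 0.1). Chance separates the groups, in either direction, for 10% of lists. The interferon list had a median of 0.04 and a mean of -0.27, the test pointing down with the mean (5 tested, camera adjusted p = 0.277), with Bst2 and Ifi27l2a at -0.78 ± 0.31 and -1.0 ± 0.42. The unfolded protein and ATF4 list had a median of -0.18 (15 tested, camera adjusted p = 0.277), with the chaperones Hsp90b1 and Hspa5 at -0.42 ± 0.22 and -0.43 ± 0.24. Immediate early and heat shock genes (15 tested, median 0.01, mean -0.12), glycolysis and hypoxia genes (12 tested, median -0.13), cholesterol synthesis genes (7 tested, median -0.02, mean 0.09), growth factors and regeneration genes (5 tested, median -0.02, mean 0.05) and cytosolic ribosomal proteins (72 tested, median 0.01) were not called either, at camera adjusted p = 0.753, 0.721, 0.755, 0.855 and 0.924, and where median and mean differ in sign the test took the sign of the mean. No member of these 9 lists passed over all genes or adjusted over the list alone. Of 26 fixed lists, 16 were tested and 14 of these were not called. The other 10 had fewer than 5 tested members. Among the latter, NF-kB response had 3, mucous and goblet programme 1 and bitter and sweet taste receptors 1. This 1 receptor gene was the umami receptor gene Tas1r1, at 1.10 ± 0.40 (edgeR adjusted p = 0.804 over all genes). As the single tested member it had no adjustment over its list, and its unadjusted edgeR p was 0.0147. Thymocyte, myeloid and dendritic, B cell and endothelial markers had 1 each and ILC2, erythroid and mitochondrially encoded ones 0.

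In simulated counts with the same depth and spread, 200 of 5135 genes were changed per draw. Here edgeR called 87.2% of genes changed 4-fold, 20.9% of those changed 2-fold and 2.73% of those changed 1.5-fold. With 200 changed genes the adjusted threshold is easier to reach than with the 3 called in the data. Simulated genes also varied independently of each other. These shares may therefore be too high for this comparison. Even so, most 2-fold changes were not detectable at this depth and number of libraries.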

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

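Leaving out a library in turn gave 1 to 20 genes higher and 0 to 15 lower. Without vehicle replicate 1 or vehicle replicate 2 the counts were 1 higher and 0 lower, without vehicle replicate 3 8 and 15, without rIL-13 replicate 1 20 and 9, without rIL-13 replicate 2 2 and 0, and without rIL-13 replicate 3 1 and 0. No filter gave 5 higher and 2 lower, DESeq2, which tested all 9088 listed genes and so differs in filter as well as tool, 4 and 2, and limma voom 0 and 0. At adjusted p under 0.1, 3 genes were higher and 2 lower. With a replicate term as a block, 8 were higher and 5 lower. Libraries of the same number correlated at -0.0676, 0.0733 and -0.223 in their deviations from the group mean. These values show no pairing by number, but they are too few to exclude a weak pairing. Other scaling factors, a total without ribosomal protein genes and 10 UMIs in 3 libraries kept 2 and 1. With vehicle replicate 3 and rIL-13 replicate 1 both left out, added after seeing the data, 21 were higher and 10 lower. The cause of these differences was not tested. With thinning to equal depth, also added after seeing the data, 20 draws called Dnaaf3 in 20, Des in 18 and Ptpn18 in 17. Over all settings genes kept both the sign of their log2 fold change and their status as past the threshold or not in 574 cases. A gene gained a call in 19 cases, lost one in 18 and turned sign in 14. These counts do not measure size, which could differ within a kept status, as for Tapbp (0.000904 to 0.49) and Col6a1 (-1.86 to -0.56). Lists kept their direction and status in 164, reversed direction in 36, lost a call in 7 and gained one in 2. Differences of shares kept their sign in 64 and reversed in 5.

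The number of lists called was 0 with an estimated correlation and 0 with fry (0.741 for the tuft and for the fibroblast list), and 1 to 3 with a library left out. The unfolded protein list was called, lower, without vehicle replicate 2 (camera adjusted p = 0.0218) and without rIL-13 replicate 1 (0.0184). The gene list tuft cell genes was called in each (2.5e-11 to 0.0129), at 5.0e-05 without Ptpn18, 3.9e-09 with the pair left out and 1.8e-06 thinned. The fibroblast list ran from 0.00237 to 0.685, and was at 0.00458 with the pair left out. Directions reversed under leaving out a library, with camera adjusted p from 0.395 to 0.918 for type 2 cytokines, 0.367 to 0.737 for cell cycle, 0.18 to 0.887 for antigen presentation, 0.255 to 0.887 for other mimetic markers, 0.555 to 0.886 for immediate early genes, 0.324 to 0.991 for glycolysis, 0.676 to 0.887 for cholesterol synthesis, 0.235 to 0.991 for growth factors and 0.357 to 0.946 for ribosomal proteins. With 10 UMIs in 3 libraries, directions reversed for STAT6 targets (camera adjusted p = 0.910), cholesterol synthesis (0.994) and growth factors (0.910). With the pair left out they reversed for STAT6 targets (0.972), other mimetic markers (0.698), glycolysis (0.972), cholesterol synthesis (0.732), growth factors (0.928) and ribosomal proteins (0.698). With thinning they reversed for STAT6 targets (0.861), cell cycle (0.927) and cholesterol synthesis (0.853), and with fry for ribosomal proteins (0.984).

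Log2 fold changes that turned sign with a library left out ran from -0.61 to 0.0360 for Cd74, -0.15 to 0.12 for Cish, -0.20 to 0.64 for Il25, -0.46 to 0.63 for Mki67, -0.41 to 0.21 for Pou2f3, -0.0908 to 0.87 for Sbsn and -0.34 to 0.17 for Tgfb1. The log2 fold change of Cish was 0.0302 with library totals, and with limma voom the log2 fold change of Mki67 was -0.11 and the log2 fold change of Pou2f3 was 0.00332. Group differences that turned, in percent, ran from -0.00391 to 0.00367 for the share of UMIs, thymocyte markers, from -0.000459 to 0.00255 for the share of UMIs, B cell markers, from -0.000850 to 0.000836 for the share of UMIs, ILC2 markers, and from -0.144 to 0.000143 for the share of UMIs, other mimetic cell markers.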

Other observations

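Beyond the fixed lists, targets of the coactivator YAP and its partner TEAD were looked at, a list prompted by the lower values of Ankrd1 and F3, which it contains. These lists, and Kit, Colca2, Wwc1 and F3 below, were chosen after values of several members were seen. Of 13 tested YAP and TEAD targets, 12 had a negative log2 fold change, with a mean of -0.44, and camera with an estimated correlation gave p = 0.102, which leaves open whether they may fall as a list. The matricellular genes Ccn1 (-0.43 ± 0.23) and Ccn2 (-0.56 ± 0.33) are known targets, and neither passed. Ccn2 was lowest in rIL-13 replicate 3, at 151 UMIs, the library that also had the lowest fibroblast score, -1.40. Mesothelial markers, such as Msln (-1.79 ± 0.59) and Upk3b (-1.47 ± 0.71), had a mean of -0.83 over 7 members, and camera with an estimated correlation gave p = 0.385, so a fall of the list might or might not be present. Vehicle replicates 1 and 2 stood apart, with 152 and 191 UMIs of Msln against 49 in vehicle replicate 3 and 35, 24 and 15 with rIL-13, and Krt19 of the same list was at 0.31 ± 0.23. Neuroendocrine genes other than Chga and Syt5 had a mean of 0.54 over 8 members, and camera with an estimated correlation gave p = 0.152, so they may or may not rise with them.

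Further genes stood out by size without passing in the filtered edgeR fit of all libraries. The receptor kinase gene Kit was at 2.07 ± 0.46, with 5, 11 and 6 UMIs with vehicle and 11, 28 and 20 with rIL-13 (edgeR adjusted p = 0.255). Colca2, which encodes a coactivator of Pou2f3, was at 1.46 ± 0.38 (edgeR adjusted p = 0.367), and Wwc1, which encodes the Hippo pathway protein KIBRA, at 1.70 ± 0.32 (edgeR adjusted p = 0.0607, and 0.0210 without a filter, where it passed). The gene of tissue factor, F3, was at -1.14 ± 0.29 (edgeR adjusted p = 0.367). Without rIL-13 replicate 1 each passed, at edgeR adjusted p = 0.0179 for Kit, 0.0119 for Colca2, 0.00705 for Wwc1 and 0.00429 for F3, and without rIL-13 replicate 2 none did, at 0.956, 1.0, 0.567 and 1.0.

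The heterogeneity tests and the test of Ptpn18 in this part were chosen only after the result was seen, and thinning was added after seeing the data. In the preset test alone, tuft cell genes were higher and fibroblast markers lower (adjusted p = 0.93 for both with an estimated correlation), and if this holds it may reflect fewer cells of other types in the rIL-13 libraries. Such a shift would raise all tuft-specific genes alike. The heterogeneity p of the tuft cell genes other than Ptpn18 was 0.0170, and 0.118 without members that other thymic stromal cells also express. The first value lies under 0.05 and the second does not, so the test cannot decide whether the members rose alike. It also takes members as independent, while the estimated correlation within the list was 0.47. An even correlation would make both p-values too large, but whether it was even was not tested. A change of composition stays open. Ptpn18 lay 4.24 standard errors above the mean of the other tuft cell genes, but it was singled out as the highest member, so this does not exclude composition. The mean log2 fold change of the tuft cell genes was 0.487 with every library thinned to the smallest total and 0.44 at full depth. Random thinning keeps the expected proportion of each gene in a library. It therefore cannot decide whether the lower depth of the rIL-13 libraries contributed to the tuft difference.

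The tests in this part, on the neighbours of chromosome 7, were all chosen only after the result was seen. Syt5, Dnaaf3 and Tnni3 were higher together, and 3.3% of 10000 random placements held 3 such genes among 5 consecutive ones, but the window was set after the cluster was seen and Tnni3 overlaps Dnaaf3, so chance stays open. Reads of Dnaaf3 and Syt5 could come from 1 transcript, or from a shared regulatory response. The ratio of Syt5 to Dnaaf3 UMIs differed over the rIL-13 libraries (exact p = 0.00293), and that of Tnni3 to Dnaaf3 over all 6 had exact p = 0.0945, but with fewer than 100 UMIs of a gene both explanations are left open.

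In this part the percentage among 191 genes was written before the result was seen, and the tests of the 31 genes and of the exchanged labels were chosen only after. Vehicle replicate 3 and rIL-13 replicate 1 correlated best with each other, and their labels might have been swapped. Of genes past an unadjusted threshold of 0.01 in the other 4 libraries, 57.6% of 191 differed between these 2 in the same direction, with a binomial interval of 50.2 to 64.7 that takes genes as independent, and of those past adjusted p = 0.05 in edgeR, 54.8% of 31, with an interval of 36.0 to 72.7. With these 2 labels exchanged edgeR called 0 genes against 3 as given, and camera called 3 lists against 2. The bound set beforehand for the 191 genes, over 50% with an interval above it, was met, but barely. Dnaaf3, Ptpn18 and Des, which also passed with both libraries left out, followed the given labels in them. Vehicle replicate 3 and rIL-13 replicate 1 had 8.68 and 107 CPM of Dnaaf3, 276 and 624 of Ptpn18, and 308 and 80.8 of Des. For these 3 genes the values go against a swap, but a fit with the given labels chose them. A swap stays open over the genes as a set, since 2 single libraries give no measure of how genes vary together. Over the 10 splits into 3 and 3, as many genes as in the real one were called in 2, the real one included (real 3, highest other 12), and as many lists in 5 (real 2, highest other 4), and 10 splits cannot give a share under 0.05. The split with 12 genes set vehicle replicates 1 and 3 and rIL-13 replicate 1 against the rest, which points to a structure of the samples other than treatment that may add to the spread.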
